A study of Homo sapiens with 10 samples.

How the data were processed

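The deposited values are probe set intensities on a linear scale, one value per probe set and array, as the authors submitted them. How the authors summarised probes into probe sets and normalised the arrays is not given in the sources used here. The values pile up at a floor of 1. They were used as deposited, without further normalization, and tests ran on log2(intensity + 16), so fold changes of dim genes are smaller than their intensity ratios. The labels state total RNA extracted with Trizol and standard Affymetrix biotin-labelled cRNA for every array.

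Of 54675 probe sets, 41091 name 1 gene, 1801 name several, 11721 name none and 62 are controls. Gene symbols were matched to the reference annotation, which updated the symbol of 11 probe sets and left 54 unmatched. Each of 19777 genes was represented by its brightest probe set on average among those naming that gene alone. A gene was tested if it lay above its array's median on at least 3 arrays, which left 14045 genes.

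Tests used limma (lmFit and eBayes) in one model of 3 groups with 7 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Counts at 2-fold also need a log2 fold change of at least 1 in size. Probe sets of ERG and ETV1 were also compared with exact two-sided permutation tests, whose smallest possible p is 0.1 for 3 against 3 arrays and 0.029 for 4 against 3. For overlap, the covariance of the log2 fold changes was set against 20 simulations of unchanged groups sharing 3 simulated control arrays, all drawn as independent noise.

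The 24 gene lists with 552 members, 41 of them not matched to a gene on the array, cover proteases and invasion, mesenchymal, epithelial junction, basal, luminal, androgen response, cholesterol synthesis, steroid metabolism, ERK feedback, WNT, TGF-beta, interferon, NF-kB and cytokine, mitosis, DNA replication, p53, squamous, hypoxia and glycolysis, amino acid and ER stress and other ETS genes, and endothelial, fibroblast, leukocyte and neuroendocrine markers. They were tested with limma's camera (preset inter-gene correlation 0.01) and adjusted over the 24 lists, and again with an estimated correlation and with fry.

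The grouping, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names 172 genes. For each comparison with control it takes the 8 largest rises and 8 largest falls among passing genes whose arrays do not overlap between groups, and 5 each way between the arrays labelled ERG and ETV1 cells. It adds 4 genes in each of the 4 direction classes of genes passing in both comparisons, and up to 3 passing members of each list. Genes always named where tested include ERG, ETV1, ETV4, ETV5, PLAU, VIM, CDH1 and EZH2. Sex-specific genes and probe sets naming several genes or none are left out.

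The alternatives were quantile normalization, median centring, no filter, a 75th percentile filter, the mean of a gene's probe sets, every probe set, only probe sets not designed to match several transcripts, limma with trend and robust, array weights, only the 2 groups compared, a replicate block, pseudocounts of 1 and 64, a threshold of 0.01, and leaving out each array in turn. In a self-test on simulated arrays, 200 genes were changed. A change of 1 on the log2 scale was recovered in 98.5%, 97.0% and 100% of genes for ERG versus control, ETV1 versus control and ERG versus ETV1, and a change of 0.5 in 31.3%, 26.9% and 35.8%, with 7, 4 and 7 false calls. The simulated genes varied independently, and far fewer were changed than passed on the real arrays, so these rates may not hold there. The software was R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.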

Results

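Expression was measured on 10 Affymetrix HG-U133 Plus 2.0 arrays in RWPE-1 cells, an immortalised, non-tumorigenic line of human prostate epithelium. The cells had been infected with retroviral vectors and selected as stable clones. Cells carrying the biotin ligase BirA alone served as controls (3 arrays), and the other clones carried BirA together with ETV1 (4 arrays) or ERG (3 arrays), ETS transcription factors that are activated by gene fusions in prostate cancer. The series design speaks of 3 biological replicates, while the labels give 4 arrays for ETV1. Since nothing says that the replicates came from separately derived clones, the p-values measure the spread between these arrays, part of which may be technical. The comparisons address which genes differ when each factor is overexpressed, and how far the responses to the 2 factors overlap. Silencing in LNCaP and VCaP cells, named in the series title, was not analysed here.

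The number of arrays limits the precision of the values. The arrays labelled ERG stood apart from the other 7. Their median intensity over all probe sets was 50.7 ± 2.09 (SD, n = 3), against 72.5 ± 1.05 (n = 3) in the control and 73.8 ± 2.01 (n = 4) in the ETV1 arrays. Spearman correlations across probe sets were 0.766 to 0.811 between arrays labelled ERG and control arrays, 0.956 to 0.969 between ETV1 and control arrays, and 0.944 to 0.961 among the arrays labelled ERG. The cre hybridisation control, a labelled transcript added to each sample in a fixed amount, read 30914 ± 1457 on the arrays labelled ERG and 15380 ± 457 on the control arrays. The ratio of the 3 prime to the 5 prime probe set of ACTB, a sign of RNA integrity and labelling, was 2.94 ± 0.171 on the arrays labelled ERG, 1.38 ± 0.0243 on the control arrays and 1.26 ± 0.0288 on the ETV1 arrays. The same ratio of GAPDH did not set the arrays labelled ERG apart, at 1.005 ± 0.0516, against 0.916 ± 0.0202 on the control and 1.02 ± 0.0253 on the ETV1 arrays. The 5 prime part of 18S ribosomal RNA, which oligo-dT priming should leave out, read 121 ± 39.7 in control, 633 ± 253 in ETV1 and 961 ± 135 in the arrays labelled ERG. On ETV1 replicate D it read 276, and on the other ETV1 arrays 680 to 874.

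**Figure D1:**
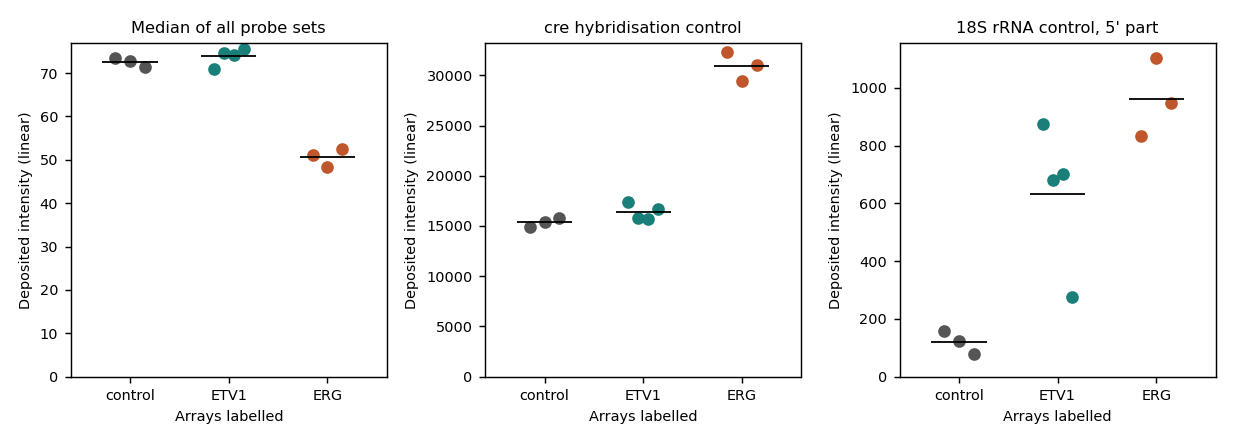
Deposited linear intensity of each array (points) and group mean (lines) for the median of all probe sets, the cre hybridisation control and the 5 prime part of 18S ribosomal RNA, in 3 control, 4 ETV1 and 3 ERG-labelled arrays. The arrays labelled ERG have a lower median, at 48.45 to 52.55, and a cre signal of 30914 on average against 15380 in control arrays.

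ETV1 was raised in the cells labelled with it. The ETV1 probe set with the largest change rose from an intensity of 88.1 ± 29.0 (SD, n = 3) in control arrays to 1320 ± 355 (n = 4), a log2 fold change of 3.67 with a standard error of 0.23 (limma adjusted p = 2.4e-06). The next ETV1 probe sets rose by 2.67 and 2.69 on the log2 scale, with limma adjusted p of 3.3e-06 and 8.2e-06. For each of these 3 probe sets the exact two-sided permutation p was 0.029, the smallest that 4 against 3 arrays can give. The remaining ETV1 probe sets differed by 0.14 and 0.19, with limma adjusted p of 0.75 and 0.60.

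ERG was not clearly raised in the arrays labelled with it. The dimmest ERG probe set in control arrays went from 9.04 ± 3.23 (n = 3) to 36.5 ± 12.3 (n = 3), a log2 fold change of 1.05 with a standard error of 0.22 (limma adjusted p = 7.7e-04). Its exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow. It read 25.68 to 49.95 on the arrays labelled ERG and at most 20.2 on any other array. Further ERG probe sets, at 25.5 and 17.2 in control arrays, differed by 0.29 and 0.34 (limma adjusted p = 0.33 and 0.11), and after quantile normalization the one at 17.2 passed with 0.51. The brightest ERG probe set fell from 186 ± 4.61 to 9.43 ± 1.57, a log2 fold change of -2.99. Because the probe sets of the named factor went opposite ways, its own gene did not settle the label, and directions drawn from these arrays below carry that limit.

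**Figure D2:**
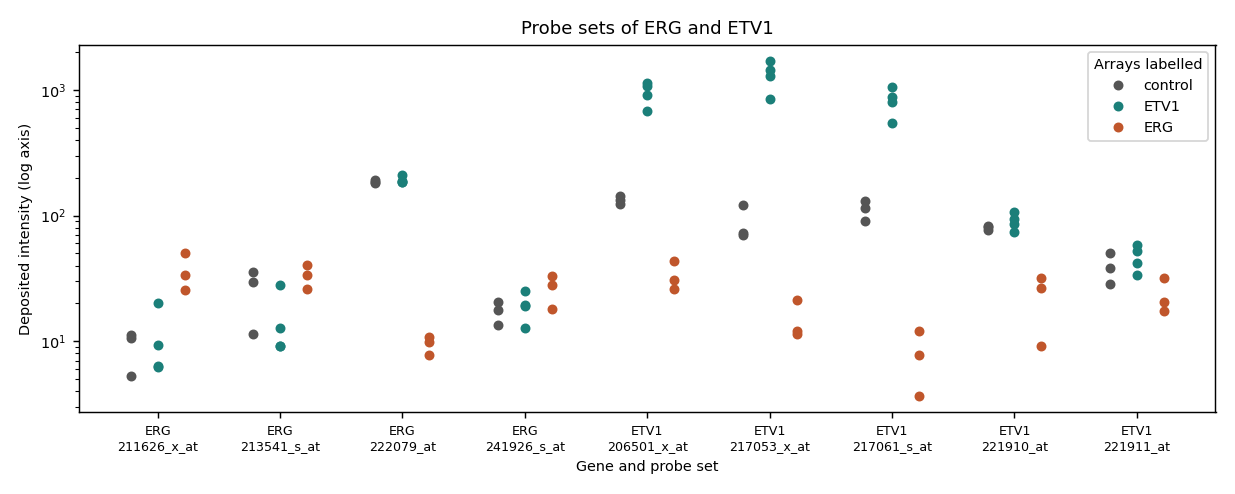
Deposited intensity (log axis) of every probe set of ERG and ETV1 on each array, in control (n = 3), ETV1 (n = 4) and ERG-labelled (n = 3) arrays. The ETV1 probe set with the largest change averages 1320 in ETV1 arrays against 88.1 in controls, while the ERG probe sets of the arrays labelled ERG average between 9.43 and 36.5.

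Single genes, each read from its brightest probe set, differed between ETV1 and control cells by up to 3.67 on the log2 scale. ALDH3A1, an aldehyde dehydrogenase of epithelia, rose from 39.0 ± 8.42 (SD, n = 3) to 776 ± 530 (n = 4), a log2 fold change of 3.67 (SE 0.30), with ETV1 replicate D at 1570. IL13RA2, a decoy cytokine receptor, rose from 142 ± 19.7 to 2058 ± 699 (log2 fold change 3.65, SE 0.27), and S100P, a calcium-binding protein, rose from 811 ± 209 to 7013 ± 534 (3.11, SE 0.20). The heparan sulfate enzyme HS3ST1 rose by 3.41, the chloride channel ANO1 by 3.36, the protease inhibitor TFPI2 by 3.33, the trypsinogen PRSS2 by 3.10 and the adenosine-producing surface enzyme NT5E by 3.09. PLIN2, which coats lipid droplets, fell from 622 ± 156 to 87.4 ± 20.4 (log2 fold change -2.62, SE 0.18). CCNE2, a cyclin of entry into DNA synthesis, fell from 915 ± 173 to 163 ± 41.3 (-2.39, SE 0.17), and UBE2T, a ubiquitin-conjugating enzyme of DNA crosslink repair, fell from 2703 ± 386 to 585 ± 55.2 (-2.17, SE 0.14). The noncoding RNA CRNDE changed by -2.33, the ubiquitin ligase RNF128 by -2.29, the nuclear envelope gene SUN3 by -2.52 and the ephrin receptor EPHA7 by -1.97. H1-10-AS1 changed by -2.59 (limma adjusted p = 0.048), but ETV1 replicate D was at the floor intensity of 1, and without it the change was -1.19. It did not pass without control replicate A (-2.50), B (-2.60) or C (-2.68), or without ERG-labelled replicate A (-2.59). In total 3551 of 14045 genes passed in limma at a Benjamini-Hochberg adjusted p of 0.05, of which 1314 were higher and 2237 lower, and 528 changed at least 2-fold (331 higher, 197 lower). Without control replicate B 2255 genes passed. The share of higher genes was 37.0% with all arrays, 52.1% without control replicate A and 24.3% without control replicate C. Among the 1147 genes with at least 2 passing probe sets, these went the same way in 96.0%, against 42.5% when probe sets were shuffled over genes.

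Genes of DNA replication fell together in ETV1 cells. Of 29 measured members 23 fell and none rose (adjusted over the list alone, 23 fell and 1 rose), with a median log2 fold change of -0.89. MCM2, a subunit of the replicative helicase, went from 3510 ± 415 (n = 3) to 1051 ± 248 (n = 4), a change of -1.74 (SE 0.16), and GINS2, a part of the same helicase complex, changed by -1.84 (SE 0.14). The list shifted against all other genes (camera adjusted p = 3.6e-13, and adjusted p = 0.30 with an estimated correlation), and its mean shift per ETV1 array was -0.71 in replicate D and -0.83 to -0.90 in the others. Of 26 mitosis genes 7 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.21). The motor protein KIF11 changed by -1.23 and the proliferation marker MKI67 by -0.86, and TOP2A, a topoisomerase, changed by -0.67 but did not pass without control replicate A (-0.53). The mean shift of the mitosis list was -0.17, and -0.05 without ETV1 replicate D. The 18S signal given above was higher in every ETV1 array than in any control array, and lowest of the ETV1 arrays in replicate D.

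Of 34 measured interferon-response genes 17 rose and 1 fell in ETV1 cells (17 and 1 adjusted over the list alone). OAS2, an antiviral enzyme that senses double-stranded RNA, rose from 452 ± 124 to 1995 ± 321 (log2 fold change 2.13, SE 0.19), the antiviral protein RSAD2 rose by 2.02 and the exonuclease ISG20 by 1.87. BST2, which tethers viruses to the cell surface and was picked out after its values were seen, fell by 0.61. The camera adjusted p was 3.4e-10, and the adjusted p = 0.38 with an estimated correlation. The mean shift per ETV1 array was 0.85 in replicate D, where 18S read 276, and 0.56 to 0.67 in the others, where it read 680 to 874. On control replicates A, B and C the same measure, taken against the control mean, was 0.06, 0.17 and -0.23. Of 19 NF-kB and cytokine genes 8 rose and none fell (8 and 0 adjusted over the list alone, camera adjusted p = 3.5e-04, adjusted p = 0.30 with an estimated correlation). They included the prostaglandin synthase PTGS2 (1.53), the neutrophil chemokine CXCL8 (1.34) and TNFAIP3, an inhibitor of NF-kB signalling (1.10). Of 18 p53 target genes 9 rose and none fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.54 with an estimated correlation). The DNA repair gene XPC rose by 1.32 and the death receptor TNFRSF10B by 0.79.

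Some mesenchymal, squamous and basal epithelial genes rose as well, in each list a minority when adjusted over all tested genes as deposited. After quantile normalization 12 mesenchymal, 7 squamous and 10 basal genes rose, and 2, 2 and 0 fell. VIM, the mesenchymal intermediate filament, rose from 1346 ± 277 (n = 3) to 6943 ± 1926 (n = 4), a log2 fold change of 2.32 (SE 0.21), and the cadherin CDH11 rose by 2.45, while the matrix protein TGFBI changed by -1.64. In the mesenchymal list 8 of 19 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.30 with an estimated correlation), and its mean shift of 0.55 was 0.29 without probe sets that can match several transcripts. Of 19 squamous differentiation genes 7 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 7.8e-04, adjusted p = 0.31 with an estimated correlation), among them the calcium-binding protein S100A9 (1.94) and the protease inhibitors SERPINB4 (1.93) and SERPINB3 (1.85). The mean shift of this list was 0.55, and 0.34 without a filter. Of 13 basal genes 6 rose and none fell, also adjusted over the list alone (camera adjusted p = 2.6e-03, adjusted p = 0.31 with an estimated correlation). The growth factor receptor EGFR rose by 0.74, whereas the rises of the keratin KRT15 (1.05) and the linker protein DST (0.98) did not pass without control replicate C (0.67 and 0.80). KRT15 also moved to 0.67 without ETV1 replicate D. Epithelial junction genes went both ways, with 4 of 25 higher and 8 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.64). The desmosomal cadherin DSG3 rose by 1.03, and the adhesion molecule EPCAM and the epithelial transcription factor GRHL1 changed by -0.89 and -0.93. CDH1, the epithelial cadherin, differed by -0.16 (limma adjusted p = 0.48).

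Several signalling and invasion genes were higher in ETV1 cells. SFRP1, a secreted modulator of WNT signalling, rose from 381 ± 62.7 (n = 3) to 2271 ± 455 (n = 4), a log2 fold change of 2.52 (SE 0.17), and the ligand WNT5A rose by 1.25. Of 19 WNT pathway genes 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 3.1e-03, adjusted p = 0.30 with an estimated correlation). The WNT list did not pass with the 75th percentile filter (adjusted p = 0.0907, range over the alternatives 5.77e-04 to 0.0907). Of 16 protease and invasion genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.31 with an estimated correlation). Without probe sets that can match several transcripts the protease list did not pass (adjusted p = 0.327, range over the alternatives 0.00207 to 0.327), and its mean shift went from 0.37 to 0.15. The plasminogen activator PLAT rose by 1.70, the protease inhibitor TIMP3 by 1.11 and the cathepsin CTSB by 1.10. PLAU, the urokinase, rose by 0.67 but did not pass without control replicate C (0.50) or ETV1 replicate B (0.57). Of 23 ERK pathway feedback genes 8 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.75 with an estimated correlation), led by the MAP kinase phosphatase DUSP4 (2.46) and the AP-1 subunit FOSL1 (1.96). That list did not pass in 5 of the alternatives. These were without control replicate B (adjusted p = 0.13, range over the alternatives 0.0049 to 0.13), without ETV1 replicate B, ETV1 replicate C or ERG-labelled replicate C, and with only the 2 groups compared. Of 18 TGF-beta target genes 6 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.26), with the activin subunit INHBA at 2.19 and the collagens COL4A2 and COL4A1 at 1.77 and 1.72.

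The lists of androgen response and steroid metabolism did not pass in ETV1 cells, while 9 of 19 cholesterol synthesis genes fell. IDI1 and DHCR7, enzymes of sterol synthesis, changed by -1.09 (SE 0.17) and -1.09 (SE 0.14), and no member of that list rose, with the same counts adjusted over the list alone (camera adjusted p = 8.3e-03, adjusted p = 0.75 with an estimated correlation). Taking the mean of each gene's probe sets ended that call (adjusted p = 0.0631, range over the alternatives 0.00185 to 0.0631), and without probe sets that can match several transcripts IDI1 differed by -0.29. Of 16 androgen response genes 2 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.86), with PMEPA1, an androgen- and TGF-beta-induced gene, at -1.33. Of 16 steroid metabolism genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.86), the cytochrome CYP1B1 at 0.63 and the dehydrogenase HSD17B10 at -0.74. Of 15 luminal genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.84). Acid phosphatase ACP3 was at -0.60, and the keratins KRT19 and KRT18, at 0.74 and -0.57, did not pass without control replicate C (0.44) and control replicate A (-0.51).

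The remaining lists did not shift in ETV1 cells. Of 20 other ETS factors 3 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.77). FLI1 rose by 1.89, or by 0.87 where leaving out ERG-labelled replicate A or C changed the probe set that stands for it, the repressor ERF rose by 1.46, and ETS1 rose by 0.88 but did not pass without control replicate C (0.75). Of 21 hypoxia and glycolysis genes 1 rose and 4 fell, and of 21 amino acid and ER stress genes 3 rose and 5 fell (1 and 4, and 4 and 5, adjusted over the list alone), with camera adjusted p of 0.64 for both. The glycolytic regulator PFKFB4 changed by -0.62 and the serine synthesis enzyme PSAT1 by -0.71. For cell types other than epithelium, none of 8 endothelial and none of 3 fibroblast markers passed, also adjusted over the list alone, and the camera adjusted p were 0.96 and 0.90. Of 6 leukocyte markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.77), and of 5 neuroendocrine markers 2 fell (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.86). In all, 11 of the 24 lists passed. Of the 35 splits of these 7 arrays into 3 and 4, 5 gave at least 11 lists, the real split included.

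**Figure D3:**
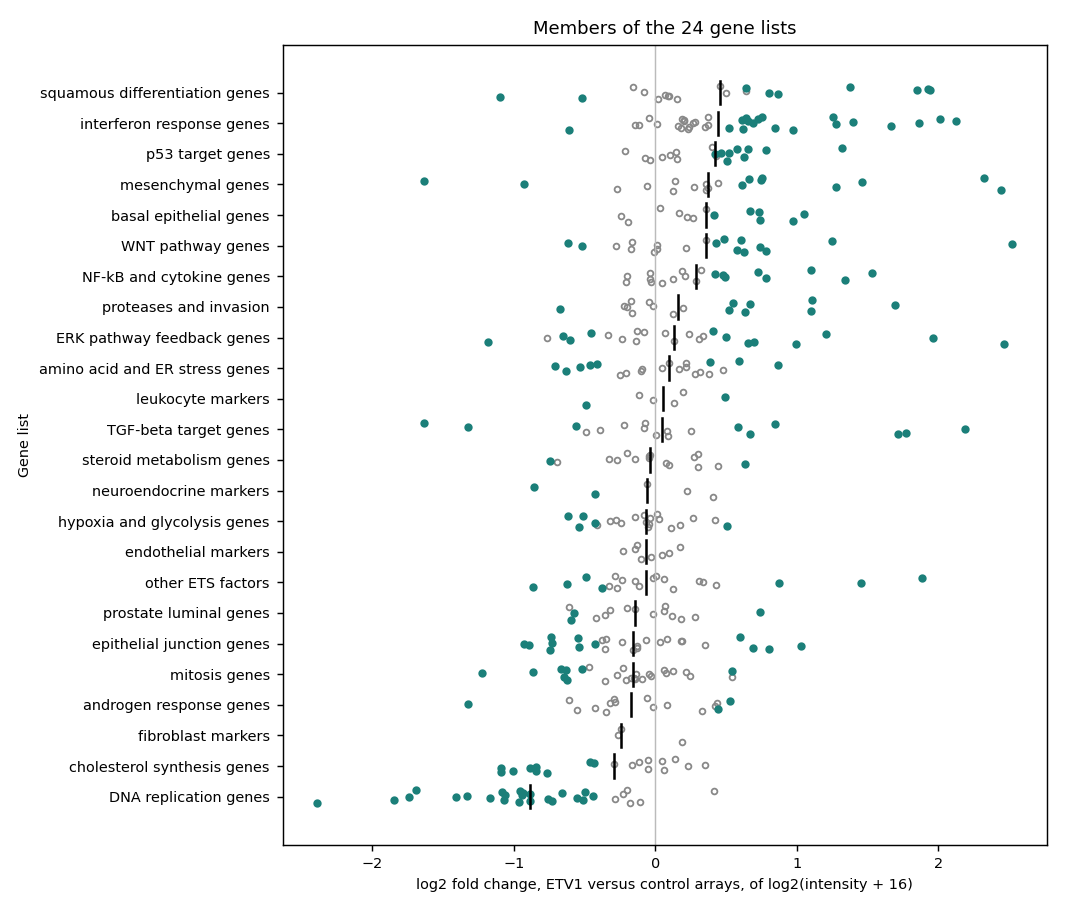
Log2 fold change of ETV1 (n = 4) versus control (n = 3) arrays for each measured member of the 24 gene lists, on log2(intensity + 16). Filled points passed at an adjusted p of 0.05 over all genes, open points did not, and black bars are list medians, which run from -0.89 for DNA replication to 0.46 for squamous differentiation.

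In the arrays labelled ERG, whose label ERG itself did not settle, mitosis and interferon-response genes were higher than in control arrays. Of 26 mitosis genes 25 rose and 1 fell (25 and 1 adjusted over the list alone), including the kinetochore genes NUF2, from 79.5 ± 17.1 (n = 3) to 930 ± 114 (n = 3), a log2 fold change of 3.32 (SE 0.20), and NDC80 (2.95), and the spindle gene DLGAP5 (2.72). Of 34 interferon-response genes 31 rose and 2 fell (32 and 2 adjusted over the list alone), with IFI6 from 1034 ± 252 to 10470 ± 1155 (3.35, SE 0.20), the immunoproteasome subunit PSMB9 (3.15) and the antiviral GTPase MX2 (2.79). The camera adjusted p were 1.0e-05 and 1.5e-04, with adjusted p = 0.93 for both with an estimated correlation. Relative to the mean of all other genes, the mean shifts were 1.78 and 1.30. These counts rest on 1 probe set per gene. After quantile normalization, 6 mitosis genes had several probe sets that all passed upward, and 3 had probe sets passing in opposite directions. For interferon-response genes these numbers were 3 and 4. These same arrays had the ACTB ratio of 2.94, the GAPDH ratio of 1.005 and the cre signal of 30914.

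The largest single differences of the arrays labelled ERG were falls of genes that were bright on the other 7 arrays. Each gene was read from its brightest probe set on average over all arrays. With 7 arrays not labelled ERG, that choice can favour probe sets that fell on the arrays labelled ERG. ALPP, the placental alkaline phosphatase, went from 2476 ± 214 (n = 3) to 1.24 ± 0.416 (n = 3), a log2 fold change of -7.17 (SE 0.13), and GLI2, an effector of hedgehog signalling, went from 3974 ± 257 to 20.7 ± 6.87 (-6.78, SE 0.15). The uncharacterised LOC728743 changed by -7.70, POM121L12 by -6.96, the sodium-calcium exchanger SLC8A3 by -6.87 and the taste receptor transporter RTP3 by -6.76. DNAJB13 changed by -6.87, while its other probe set differed by 0.13. The dimmer probe sets of LOC728743, POM121L12, SLC8A3 and RTP3 changed by -0.98, -1.54, -1.19 and -1.54, and those of GLI2 were at -1.40 and 0.31. The ubiquitin ligase SMURF1 changed by -6.85, but differed by 0.03 without probe sets that can match several transcripts. Among rises, the Mediator subunit MED18 went from the floor of 1 on every control array to 643 ± 99.8 (5.27, SE 0.18) and the chemokine CCL20 from 104 ± 36.1 to 3168 ± 489 (4.77, SE 0.29). IFI27L2 rose by 4.80, the antimicrobial protein S100A7 by 4.73, SMIM30 by 4.59, S100A9 by 4.44, the protease TMPRSS4 by 4.42 and the glutaminyl cyclase QPCT by 4.37.

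Of 14045 genes, 11223 passed in limma (6703 higher, 4520 lower), and 6039 changed at least 2-fold. The median log2 fold change of all genes was 0.29 as deposited, 0.05 after quantile normalization and 0.70 after median centring. The share of higher genes was 59.7%, but 71.1% of 11979 passing genes after median centring, and 52.4% of 10615 after quantile normalization. Among the 4989 genes with at least 2 passing probe sets, these went the same way in 49.7%, against 39.5% when probe sets were shuffled over genes. After quantile normalization 1755 genes had at least 2 probe sets above the filter with all of them passing in one direction, 1007 higher and 748 lower, a requirement chosen after seeing the data.

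**Figure D4:**
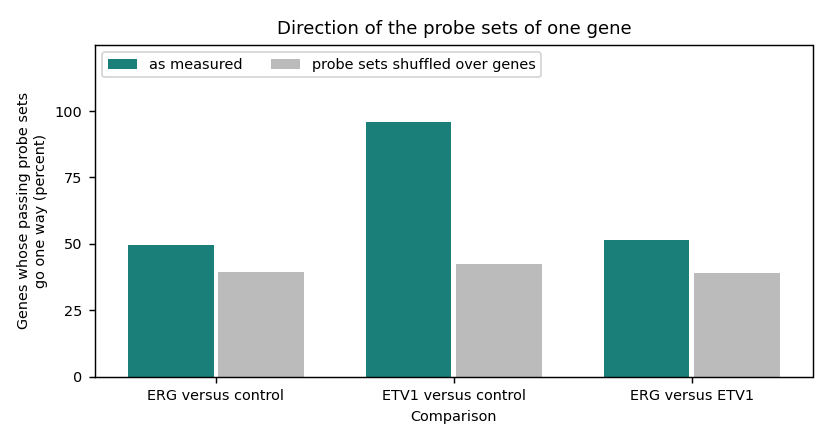
Percent of genes with at least 2 passing probe sets whose passing probe sets go one way, as measured and with probe sets shuffled over genes, in the 3 comparisons. The value is 96.0% for ETV1 versus control but 49.7% for ERG-labelled versus control arrays, where shuffling gives 39.5%.

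Some markers of other cell types, each read from its brightest probe set, were lower on the arrays labelled ERG. As above, that choice of probe set can favour falls on these arrays. The lymphocyte gene CD3E changed by -1.98, the fibroblast surface protein THY1 by -1.63 and the endothelial receptor KDR by -1.77. The endothelial adhesion molecule PECAM1 changed from 1393 ± 91.5 (n = 3) to 163 ± 10.8 (n = 3), by -2.98 (SE 0.13), but its 4 dimmer probe sets differed by -0.09 to 0.77. The collagen COL1A1 and the proteoglycan DCN changed by -2.23 and -1.86, while other probe sets of each passed in the opposite direction, at 0.87 and 1.71. Of 8 endothelial markers 6 fell and 1 rose (7 and 1 adjusted over the list alone), of 6 leukocyte markers 5 fell and 1 rose (5 and 1), and of 3 fibroblast markers all 3 fell (3 and 0). Their camera adjusted p were 0.034, 0.034 and 0.044, with adjusted p = 0.41, 0.49 and 0.41 with an estimated correlation, and after quantile normalization each was 0.0971. Over the alternatives these adjusted p ranged from 0.0174 to 0.583, 0.0174 to 0.142 and 0.0187 to 0.560, and the mean shifts of -1.29, -1.46 and -1.97 came as near to none as -0.56, -0.83 and -0.51. Without ERG-labelled replicate B none of these 3 lists passed (adjusted p = 0.0523 for each), nor did the leukocyte list without replicate C (0.0596). The androgen response list had 6 of 16 members higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.94) and the steroid metabolism list 9 of 16 higher and 5 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.94), with the dehydrogenase HSD17B11 at 2.38. The sterol enzymes MVK and SC5D were at -1.73 and 1.76, but the mean of their probe sets gave 1.10 and -0.17. The glucose transporter SLC2A1 was at -2.40, and at 0.33 without probe sets that can match several transcripts. VIM was at 0.98, and at 0.38 after quantile normalization, where it did not pass.

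The remaining lists did not pass in the arrays labelled ERG, and counts adjusted over the list alone were the same unless given. NF-kB and cytokine genes had 14 of 19 members higher and 4 lower (camera adjusted p = 0.124), among them the cytokine IL1B at 2.63, and squamous genes had 12 of 19 higher and 4 lower (0.191), with S100A8 at 3.83. Other ETS factors had 11 of 20 higher and 3 lower (0.268), with ERF at 3.90. Mesenchymal genes had 7 of 19 higher and 10 lower (0.268), and neuroendocrine markers 1 of 5 higher and 4 lower (0.124). Luminal genes had 5 of 15 higher and 7 lower (0.513), hypoxia genes 12 of 21 higher and 4 lower (0.527), and p53 targets 10 of 18 higher and 4 lower (0.680). Cholesterol synthesis genes had 10 of 19 higher and 3 lower (8 and 3 adjusted over the list alone, 0.680). Amino acid and ER stress genes had 10 of 21 higher and 2 lower (9 and 2 adjusted over the list alone, 0.847), and DNA replication genes 14 of 29 higher and 7 lower (0.898). Epithelial junction genes had 14 of 25 higher and 6 lower (0.935). The camera adjusted p was 0.936 for proteases (8 of 16 higher, 5 lower), basal genes (3 of 13 higher, 5 lower), WNT genes (9 of 19 higher, 7 lower), TGF-beta targets (9 of 18 higher, 3 lower) and ERK feedback genes (8 of 23 higher, 6 lower, or 7 and 6 adjusted over the list alone). Some of these balances turned over with the scaling. After quantile normalization junction genes had 6 higher and 12 lower, amino acid and ER stress genes 3 and 10, and p53 targets 4 and 7. DNA replication genes then had 8 and 11, ERK feedback genes 5 and 8, and TGF-beta targets 5 and 5. NF-kB and squamous genes stayed mostly higher, at 12 and 3 and at 13 and 3.

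ETV1 cells and the cells of the arrays labelled ERG shared some of the genes that differed from control. NT5E rose by 2.76 in the arrays labelled ERG and by 3.09 in ETV1 arrays, TFPI2 by 2.66 and 3.33, the galectin LGALS1 by 2.86 and 2.49, and the chemokine CXCL11 by 3.53 and 2.09. The histone gene H3-3A changed by -3.20 and -1.45, GPRIN1 by -1.70 and -1.48 and KLHL23 by -1.44 and -1.47. In the opposite sense, SUN3 was at 3.11 and -2.52, CXXC5 at 1.45 and -1.50, the centromere gene CENPM at 1.53 and -1.40 and the fatty acyl reductase FAR2 at 1.39 and -1.45. The antioxidant enzyme GPX3 was at -2.90 and 2.41 (its dimmer probe set at -1.51 and 4.29), AGR2, a protein of secretory epithelia, at -2.04 and 2.01, LIMCH1 at -1.97 and 2.01 and SLITRK6 at -3.35 and 1.84.

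In both comparisons 2733 genes passed, 1149 in the same direction (808 higher, 341 lower) and 1584 in opposite directions (1330 higher in the arrays labelled ERG and lower in ETV1, 254 the reverse). Independent lists of these sizes would share 627 higher, 720 lower, 1068 and 423 genes in the same order. Across genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.013 and their covariance 0.0073. Unchanged groups were simulated with 3 simulated control arrays shared by both, every array drawn as independent noise. They gave a correlation of 0.535, a covariance of 0.0143 and 0 shared genes in limma. Such noise gives hardly any passing genes, so the 0 shared genes carry no weight. The covariance lay 0.0070 below the simulated one as deposited (difference -0.0070), and 0.0234 above it after quantile normalization, where 1735 genes passed in the same and 1582 in opposite directions. The 3 real controls cannot be split into groups of at least 2, so part of any excess of shared genes over independent lists may come from sharing them. The simulated covariance allows for that sharing only under independent noise. Without control replicate A, 879 genes passed in opposite directions, and without control replicate B 889.

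Set directly against ETV1 cells, the arrays labelled ERG had higher mitosis and DNA replication genes and lower mesenchymal genes. Of 26 mitosis genes 25 were higher and 1 lower, of 29 replication genes 25 were higher and 2 lower, and of 19 mesenchymal genes 5 were higher and 12 lower, and these counts were the same adjusted over each list alone. The camera adjusted p were 1.2e-05, 5.6e-03 and 0.029, with adjusted p = 0.84, 0.94 and 0.60 with an estimated correlation. After quantile normalization, 7 mitosis genes had several probe sets that all passed upward, and 2 had probe sets passing in opposite directions. Of the replication genes 6 had them all upward, 2 all downward and 6 in opposite directions. Over the alternatives the adjusted p of the mesenchymal list ranged from 0.0112 to 0.454, it did not pass in 3 of them, and its mean shift went from -0.97 to -0.33 with the mean of the probe sets. KIF11 differed by 2.96, GINS2 by 1.94 and CDH11 by -4.27. The dimmer probe sets of CDH11 differed by -0.37 (limma adjusted p = 0.19), -1.18 and -1.04. On the arrays labelled ERG against control arrays, its brightest probe set was at -1.82 and a dimmer one at 1.56, and both passed. Leukocyte markers (0 higher and 5 lower of 6, also adjusted over the list alone) and endothelial markers (1 and 6 of 8, also adjusted over the list alone) had camera adjusted p of 0.029 and 0.036, with adjusted p = 0.56 and 0.49 with an estimated correlation. Each did not pass in 3 alternatives, over which the adjusted p ranged from 0.0112 to 0.0891 and from 0.0108 to 0.525, and the mean shift of the endothelial list went from -1.30 to as little as -0.48. The largest differences were SUN3 (5.63), SMIM30 (5.21), IFI27L2 (4.85), S100A7 (4.81) and CCL20 (4.72) upward and LOC728743 (-7.56), ALPP (-7.32), the calcium channel subunit CACNG5 (-7.07, its dimmer probe set 0.84), DNAJB13 (-6.84) and RTP3 (-6.74) downward. ETV1 itself differed by -4.28 in its brightest probe set. Part of this was a fall on the arrays labelled ERG, where that probe set was at -1.61 against control arrays. The other ETV1 probe sets were also lower there, at -0.49 to -2.42. In limma 11746 genes passed (7082 higher, 4664 lower), 60.3% of them higher. The share was 70.9% of 12250 after median centring and 53.3% of 11246 after quantile normalization. Of genes with at least 2 passing probe sets, 51.5% had these going one way. In all, 5 of the 24 lists passed, and 9 of the 35 splits of these 7 arrays into 3 and 4 gave at least 5 lists, the real split included. Of the other genes fixed for naming, the ETS factor ETV4 differed by -0.52, ETV5 differed by -0.28 in its brightest probe set (limma adjusted p = 0.0997) and by -1.67, -1.01 and -0.89 in 3 others that passed, and the histone methyltransferase EZH2 by 1.57.

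The lists that did not pass between the arrays labelled ERG and ETV1 cells went both ways, and counts adjusted over the list alone were the same unless given. Interferon-response genes had 22 of 34 members higher and 3 lower (camera adjusted p = 0.067), and CXCL11, which is not in that list, was at 1.44. After quantile normalization 11 interferon-response genes were higher and 9 lower (camera adjusted p = 0.75), and the mean shift went from 0.638 to 0.158. Fibroblast markers had 3 of 3 lower (0.0527), though other probe sets of COL1A1 and DCN passed in the opposite direction, at 1.43 and 1.79. The mean shift of the fibroblast list was -1.91, and -0.53 without a filter. Cholesterol synthesis genes had 13 of 19 higher and 3 lower (14 and 3 adjusted over the list alone, 0.186), with FDPS at 2.29 (SE 0.15), and neuroendocrine markers 1 of 5 higher and 3 lower (0.186). Other ETS factors had 13 of 20 higher and 2 lower (0.318), with ERF at 2.44. The camera adjusted p was 0.390 for basal genes (3 of 13 higher, 7 lower) and WNT genes (6 of 19 higher, 9 lower), where SFRP1 differed by -3.60, and 0.394 for hypoxia genes (15 of 21 higher, 3 lower). It was 0.492 for proteases (5 of 16 higher, 6 lower), luminal genes (7 of 15 higher, 7 lower), ERK feedback genes (8 of 23 higher, 10 lower), NF-kB genes (12 of 19 higher, 5 lower) and p53 targets (5 of 18 higher, 7 lower). After quantile normalization p53 targets had 2 higher and 14 lower, and that list passed (camera adjusted p = 0.0223). Proteases then had 2 higher and 9 lower, ERK feedback genes 3 and 14, and NF-kB genes 10 and 6. Junction genes had 12 of 25 higher and 5 lower (11 and 5 adjusted over the list alone, 0.648), TGF-beta targets 8 of 18 higher and 7 lower (0.655), and squamous genes 10 of 19 higher and 7 lower (11 and 7 adjusted over the list alone, 0.695). Amino acid and ER stress genes had 11 of 21 higher and 5 lower (0.803). After quantile normalization 4 of them were higher and 13 lower (camera adjusted p = 0.0891), and junction genes had 11 higher and 12 lower. Androgen response genes had 8 of 16 higher and 6 lower, and steroid metabolism genes 7 of 16 higher and 5 lower (0.945 for both).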

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

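The tests of array handling and scaling for the arrays labelled ERG, of scaling for DNA replication genes and of fewer dividing cells were chosen after the result was seen.

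ETV1 replicate D stood apart from the other 3 ETV1 arrays in 23 of the 189 groups of 4 ETV1 values tested. Chance gives an outlier on any of the 4 arrays in about 1 in 20 groups, while all 23 outliers here were of replicate D. Genes can move together, so these groups are not independent. On the log2(intensity + 16) scale it was higher for ALDH3A1 (10.63, others 8.99 to 9.09), KRT15 (9.676), S100A8 (10.54), TIMP3 (9.882), CXXC5 (8.341) and RNF128 (6.661). It was lower for CDH11 (8.184), CENPN (7.836), COL4A1 (8.625), CRNDE (7.237), CXCL11 (7.192), ETS1 (9.28), HS3ST1 (8.037), INHBA (8.431) and ISG20 (9.35). It was also lower for PHLDA1 (9.29), PMEPA1 (9.162), QPCT (5.04), SUN3 (5.22), TFPI2 (9.126), TNFAIP3 (8.63) and TOP2A (9.525). H1-10-AS1 read 4.087, the floor intensity of 1, against 9.37 to 9.891. Of 5866 tested probe sets without a single gene name, 248 were higher and 300 lower in ETV1 than in control arrays. The 5 prime part of 18S ribosomal RNA was 5.246-fold higher in ETV1 and 7.973-fold higher in ERG-labelled arrays than in control arrays, and the cre hybridisation control was 2.01-fold higher in ERG-labelled arrays.

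The arrays labelled ERG differed from controls in 11223 genes. Scaling alone as the cause is argued against by the 10615 genes that passed after quantile normalization. Array handling (labelling, hybridisation or scanning) may account for a large part, since the 4 hybridisation controls were higher by a mean log2 of 0.8307 and only 49.73% of genes with at least 2 passing probe sets had these going one way. Those controls are added already labelled, so they do not bear on labelling. The split of these 6 arrays as labelled gave 11223 genes and the highest other split 0, with too few splits (1 of 10) for a share under 0.05. A biological effect of ERG stays open and is confounded with these arrays.

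DNA replication genes were lower in ETV1 arrays. Scaling alone is argued against by a mean shift of -0.8249 after quantile normalization over control and ETV1 arrays. Ribosomal RNA in the samples stays open, because the 18S signal was higher in every ETV1 array than in any control array. Replicate D, with the lowest 18S signal of the ETV1 arrays, had 0.8288 of the mean shift of the other 3, which runs against it, but a single array excludes nothing. Fewer dividing cells may also be part of it, but the mean change of mitosis genes lay 0.6477 above that of replication genes (gene permutation p = 2e-05, exact array permutation p = 0.057). The gene permutation takes genes as independent, while the estimated correlations within these lists were 0.629 and 0.43, so only the array permutation measures the spread between arrays. Replicate D (-0.74) lay nearer the controls (-0.89 to -0.95) than the other ETV1 arrays did (-0.10 to -0.13). Fewer dividing cells and an effect of ETV1 itself thus stay open.

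No ERG probe set was clearly raised in the arrays labelled ERG. The dimmest of them rose by 1.05. It passed in each setting tried for it, with changes from 0.79 (array weights) to 1.46 (median centring). Of 3604 probe sets of like intensity in control arrays, 16.59% rose by at least as much on the same arrays. Those rises may come from array handling (labelling, hybridisation or scanning) or from biology, so the share cannot tell what made this rise. The fall of the brightest ERG probe set was not set against probe sets of like intensity. A transcript lacking the probed part of ERG, or a label that is wrong, was not tested.

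Other splits of the arrays bear on the counts. For ETV1 versus control the real split gave 3551 genes and the highest other 713, and for ERG versus ETV1 11746 against 7804. In both, only the real split was as large (1 of 35), the smallest share these splits can give. The arrays thus differed by label. The splits cannot tell what made them differ, since nothing says that the replicates came from separate clones. For the gene lists chance is not excluded, with 5 of 35 splits giving at least the 11 lists of ETV1 versus control (highest other 11), and 9 of 35 the 5 lists of ERG versus ETV1 (highest other 7). For ERG versus control 5 lists passed and the highest other split gave 5 (2 of 10), with too few splits for a share under 0.05.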

How the results depend on the processing

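The requirement of 2 agreeing probe sets and the quantile normalization within the 2 groups were tests chosen after the result was seen. Among named genes, 1191 of the values under other settings kept direction and side of the threshold for ERG versus control, 1089 for ETV1 versus control and 117 for ERG versus ETV1, and 1039, 941 and 97 when 1 array was left out. The call was lost in 8 values for ERG versus control and 41 for ETV1 versus control under other settings, and in 48 for ETV1 versus control when 1 array was left out. It was gained in 4, 5 and 1 of these. For ERG versus control, 5 reversed: MVK, ERG versus control (1.098) and SC5D, ERG versus control (-0.1662) with the mean of the probe sets, and SC5D (-2.092), SLC2A1, ERG versus control (0.3291) and SMURF1, ERG versus control (0.03332) without probe sets matching several transcripts. Other probe sets then stand for the gene. The cause of the other changes was not tested.

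Gene lists called by camera with an estimated correlation numbered 0, 0 and 0 for ERG versus control, ETV1 versus control and ERG versus ETV1, against 5, 11 and 5 with the preset one, while fry gave 11 directional calls for ERG versus control, 17 for ERG versus ETV1, and 24, 22 and 24 mixed. Lists called for ERG versus control numbered 2 after quantile normalization, 3 without a filter, 2 with the mean of probe sets, 3 without probe sets matching several transcripts and 3 with array weights, and for ERG versus ETV1 2 with the mean and 3 without such probe sets. The ERG probe set at 17.2 in control arrays moved to 0.5138 after quantile normalization and 0.7483 after median centring, where the one at 25.5 moved to 0.7021, and each then passed. With the 75th percentile filter, which tests fewer genes, 7159 (ERG versus control) and 7568 (ERG versus ETV1) genes passed. Array weights gave 9850 genes for ETV1 versus control, 4089 shared in the same and 4648 in opposite directions. Estimation of these weights stopped before convergence, and the cause was not tested. At 0.01, 1992 genes passed for ETV1 versus control, 596 shared in the same and 751 in opposite directions. Genes shared in the same direction numbered 1735 after quantile normalization and 1863 with every probe set. With 2 agreeing probe sets 1755, 815 and 2129 genes passed, and with quantile normalization within the 2 groups 9975, 5229 and 10842.

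Leaving out each array gave 10170 to 11181 genes for ERG versus control, 2255 to 4140 for ETV1 versus control (lowest without control replicate B), 10688 to 11826 for ERG versus ETV1, 879 to 1931 shared in opposite and 767 to 1284 in the same direction, 2 to 5, 10 to 11 and 5 to 7 lists, and 0.2248 to 0.4926 for the ERG probe set at 17.2, which passed without ERG-labelled replicate B (0.4926). With the replicate letter as a block 11151, 3143 and 11437 genes passed. Arrays of the same letter correlated at -0.055, -0.036 and -0.094 between the ERG-labelled and control arrays and 0.089, -0.028 and -0.006 between ETV1 and control arrays, so the letters do not pair the arrays. Signal near background limits dim genes, whose changes are understated by the added 16.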

Other observations

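The gene families in this part were tests chosen after the result was seen. They were picked by the start of the gene symbol, so a family can hold genes that only share it and can miss some members.

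Genes of the SERPINB family were higher in ETV1 than in control cells. Of 7 measured members 6 rose and none fell, with a median log2 fold change of 1.68 (camera adjusted p = 3.2e-07, adjusted p = 0.11 with an estimated correlation), and a mean shift of 1.45 after quantile normalization. SERPINB4 and SERPINB3 rose by 1.93 and 1.85 (4 against 3 arrays). Of 23 collagen genes 6 rose and 1 fell (camera adjusted p = 0.0455, adjusted p = 0.58 with an estimated correlation).

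Mitochondrial ribosome genes (MRPL and MRPS) had 29 of 75 members lower and 1 higher in ETV1 cells (camera adjusted p = 7.2e-05, adjusted p = 0.58 with an estimated correlation), and a mean shift of -0.251 that was -0.1762 after quantile normalization, so scaling as a part of it stays open. Genes with PSM symbols, which include proteasome subunits, had 19 of 42 lower and 2 higher (8.1e-05, adjusted p = 0.58 with an estimated correlation, mean shift -0.277, or -0.189 after quantile normalization). Genes with NDUF symbols, which include those of respiratory complex I, had 14 of 41 lower and 1 higher (1.8e-03, adjusted p = 0.58 with an estimated correlation, mean shift -0.231, or -0.13 after quantile normalization). Genes with RPL and RPS symbols, which include cytosolic ribosomal proteins, had 2 of 35 (RPL) and 0 of 31 (RPS) lower and none higher. In the arrays labelled ERG, where 6703 of all 14045 genes were higher, 67 of the 75 mitochondrial ribosome genes were higher and 1 lower (camera adjusted p = 4.8e-07, adjusted p = 0.79 with an estimated correlation).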
